A study of Mus musculus with 12 samples.

How the data were processed

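RNA was measured in 12 islet libraries, 3 in each of 4 groups (untreated, and 1, 3 and 5 DPA after diphtheria toxin). Per the labels' protocols, RNA was extracted with RNeasy Mini columns and libraries were made with a QIAseq stranded mRNA kit. The authors deposited whole-number read counts per gene and library, per the file headers, with Ensembl identifiers. The build was mm10, per the submitters' processing notes. The aligner, the counter, the annotation release and whether counting used strand are not given in the sources used here. Of the deposited table, 12 count columns were used and 36 other columns of per-sample values (normalized units of the same libraries) were not used.

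Libraries were grouped by their labels. Nothing says that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of replicates differed by as little as sampling noise. Of 48709 genes, 17294 passed edgeR's filterByExpr (minimum count 10). Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model (robust, all 12 libraries, 1 mean per group), and differences were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. CPM values are given as mean ± SD. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Coordinates came from the GENCODE M21 annotation of mm10, where 48349 gene identifiers matched, 17257 of those tested.

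The 26 gene lists (399 members, 2 not matched by symbol) were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation and with fry. Named genes followed a rule: for each comparison with CTRL, among genes called, with an average log2 CPM of at least 1 and every treated library above (or below) every CTRL library, the 6 largest rises and 6 largest falls, leaving out predicted and clone-named genes; up to 3 called members of smallest p per list; and Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Mki67, Top2a and Cdkn1a always. Chance gives groups that do not overlap for 10% of genes with 3 against 3. Some genes that the rule names are not reported here. Between times the 4 largest changes each way and the members named against CTRL were taken. Groups, comparisons, tests, this rule and the other settings to try were fixed before the data were examined.

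The other settings were DESeq2, limma-voom, RLE scaling, library sizes without the 50 most abundant genes, no filter, only the 2 groups compared, the replicate number as a block, an acinar score covariate and leaving out each library in turn. Macrophage and stromal score covariates (mean log2 CPM of the list, prior count 2) were chosen after seeing the data. With its own score a list loses its call by design. Insulin, acinar and mitochondrial shares (the last unplanned) were compared by exact permutation tests, and over the groups with 100000 resamples. Floors of 3 counts and 95% intervals cover counting error only. The replicate numbers in the labels pair the 3 and 5 DPA libraries by the data alone: the deviations from the group means of all 3 same-number pairs correlated above 0.1 (0.156 to 0.326), which they did for no other pair of groups. This was judged per pair of groups only after the calls of both fits were known, and first over the 18 same-number pairs together. The block was fitted over all 12 libraries. Overlaps were set beside 20 simulations of unchanged groups. Splits of the 12 libraries were limited to 40 draws by computing time (60 were intended).

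Some rules were set after values were seen. List directions under other settings were counted only for called lists, a rule set after reversals had been counted. The clock gene test uses 4 opposite-phase genes. It had for a time been narrowed to Arntl and Nfil3 at 1 DPA, both already known to be higher, which fixed its outcome; the 4-gene test at both times was restored, and the rule that a median near 0 decides nothing was added then. For the mitosis genes a rule excluding stromal cells or macrophages as the whole cause by camera's kept call was tried with all values known, then withdrawn, since edgeR's and fry's calls had ended. Leave-one-out fits of the genes that differ between times were also added late.

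The fit was tested on simulated counts with known changes for 17041 genes. At a log2 fold change of 1 it recovered 86% of changed genes for 1 DPA against CTRL, 84% for 3 DPA and 80% for 5 DPA, and at -1 it recovered 72%, 66% and 68%; 6 of 139, 4 of 131 and 9 of 144 calls were false. Reads of near-identical genes, such as histone genes or Ins1 and Ins2, may have been split between copies by the authors' counting.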

Results

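Gene expression was measured by RNA sequencing of pancreatic islets from female mice of the immunodeficient NSG background that carried 1 copy of the RIP-DTR transgene, which places the diphtheria toxin receptor under the rat insulin promoter and so makes beta cells sensitive to the toxin. Libraries came from 4 groups of 3: untreated mice (CTRL) and mice given diphtheria toxin and labelled 1, 3 or 5 DPA, read here as days post-ablation. Total counts for replicates 1 to 3 were 38700773, 44764274 and 45571879 in CTRL and 38942407, 38102956 and 29867083 at 1 DPA. They were 46081176, 35774473 and 48568665 at 3 DPA and 49388420, 50012558 and 35354631 at 5 DPA. Of 48709 genes, 17294 had enough counts to be tested.

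The insulin genes Ins1 and Ins2 took 17.2% ± 1.40 of all counts in CTRL (SD, n = 3), 12.6% ± 1.96 at 1 DPA, 16.1% ± 1.51 at 3 DPA and 16.5% ± 2.75 at 5 DPA. The 1 DPA libraries all lay below the CTRL libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows), those at 3 and 5 DPA overlapped them (p = 0.5 and 0.7), and the 4 groups did not differ past the threshold (permutation p = 0.0762). Genes of acinar cells, the enzyme-secreting cells that surround islets, took 4.36% ± 3.11 of counts in CTRL and 3.02% ± 2.46, 1.01% ± 0.481 and 2.09% ± 1.38 at 1, 3 and 5 DPA (permutation p = 0.309 over the 4 groups, n = 3 each). Genes of the mitochondrial genome took 2.48% ± 0.160 of counts in CTRL and 1.66% ± 0.0867, 2.14% ± 0.188 and 2.04% ± 0.0750 at 1, 3 and 5 DPA (permutation p = 0.00108 over the 4 groups, n = 3 each). All 1 DPA and all 5 DPA libraries lay below the CTRL libraries (two-sided exact permutation p = 0.1 each). Macrophage markers averaged 4.81 and 4.32 log2 CPM in CTRL replicates 1 and 2 and 2.82 in CTRL replicate 3, and stromal markers 6.46, 6.18 and 4.70. The same scores were 2.56, 2.50 and 2.85 (macrophage) and 5.01, 5.20 and 5.34 (stromal) at 1 DPA, 4.53, 3.77 and 4.41 and 6.36, 6.05 and 6.46 at 3 DPA, and 5.04, 5.02 and 5.52 and 7.32, 6.69 and 6.82 at 5 DPA. CTRL replicate 3 also lay apart on the first principal component, at -7.03 against -72.1 and -55.3 for the other controls. Across all 4 groups 9933 genes differed (edgeR F-test, adjusted p under 0.05).

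The first comparison asks how islets had changed 1 day after an ablation that the series description calls partial; beta cell numbers were not analysed here. Insulin-like growth factor 2, Igf2, rose 68.1-fold, from 12.7 ± 2.55 CPM (counts scaled to a common library total) in CTRL to 865 ± 328 at 1 DPA (mean ± SD, n = 3; log2 fold change 6.09 ± 0.40 SE, edgeR adjusted p = 1.56e-06). Slc2a2, the glucose transporter of mouse beta cells, fell from 1038 ± 93.5 to 507 ± 60.7 CPM (log2 fold change -1.03 ± 0.12, adjusted p = 1.98e-05), and Ins1 fell from 48038 ± 3846 to 27398 ± 7038 CPM (-0.81 ± 0.18, adjusted p = 0.00264). Aen, a nuclease gene induced by p53, rose from 33.8 ± 1.95 to 167 ± 5.53 CPM (2.31 ± 0.09, adjusted p = 3.88e-08), and Nr4a1, an immediate early transcription factor, rose from 31.2 ± 16.5 to 948 ± 216 CPM (4.93 ± 0.43, adjusted p = 1.01e-05). In all, 8916 genes changed, 5045 higher and 3871 lower, beside mitochondrial shares of 1.66% against 2.48% in CTRL. With library sizes counted without the 50 most abundant genes the split was 4221 higher and 5498 lower, so the share higher went from 56.6% to 43.4% while the median log2 fold change of all genes moved from -0.05 to -0.17. With the macrophage score as a covariate 6001 of these 8916 were called and 330 had the other direction.

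Among the largest rises at 1 DPA by the naming rule were genes barely seen in CTRL. Hist1h2ad, a histone H2A gene on chromosome 13 (23574381 to 23574952, mm10), had 0 counts in CTRL and was at least 350-fold higher, and Hormad2 was at least 127-fold higher, each against a floor of 3 counts over the CTRL group. Mc1r had 1 count in CTRL and 548 at 1 DPA, a ratio of 649 (95% interval 116 to 25675), and Cfap53 had 2 against 425, a ratio of 252 (69.2 to 2084). Amhr2 rose from 0.0580 ± 0.0510 to 15.3 ± 5.83 CPM (log2 fold change 8.01 ± 0.61, edgeR adjusted p = 1.70e-06). Igf2os rose from 0.343 ± 0.0372 to 264 ± 113 CPM (9.57 ± 0.53, adjusted p = 7.52e-07). It is antisense to Igf2 (chromosome 7, 142659693 to 142670356, plus strand, against 142650766 to 142666816, minus, mm10). Upstream of Igf2 lies Ins2 (142678656 to 142743381, minus). Mc1r, Cfap53 and Amhr2 each have an expressed same-strand gene within 10 kb upstream. Read-through into these was not tested singly. Strand use in counting is unknown, so Igf2 and Igf2os reads cannot be told apart.

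The 6 largest falls at 1 DPA by this rule were those of Samsn1 (log2 fold change -4.62 ± 1.58), the alarmin Il33 (-4.06 ± 1.25), lymphotoxin beta, Ltb (-4.02 ± 1.27), Mmrn1 (-4.11 ± 1.30), Clca3a1 (-3.37 ± 1.01) and the nucleotide receptor P2ry13 (-3.36 ± 0.96). edgeR called them lower (adjusted p 0.0138 to 0.0347). Without 1 DPA replicate 1, 2 or 3 the calls of Samsn1, Mmrn1, Il33, Ltb and Clca3a1 ended, as did those of Samsn1, Mmrn1, Il33 and Ltb without CTRL replicate 1 and that of Mmrn1 without CTRL replicate 2 (adjusted p 0.0531 to 0.117). With the macrophage covariate none of these 6 was called, and Samsn1, Il33 and Ltb turned to 0.19, 0.18 and 0.10.

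Of 18 beta cell genes 13 fell and 1 rose at 1 DPA, also when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.769 with an estimated correlation). Glp1r, the GLP-1 receptor, fell (log2 fold change -0.78 ± 0.11). Pdx1, a beta cell transcription factor, fell (-0.34 ± 0.11, edgeR adjusted p = 0.0235), a call that ended without CTRL replicate 3, 1 DPA replicate 2 or 1 DPA replicate 3 (adjusted p 0.0505 to 0.0812). Ins2 (-0.37 ± 0.16) and Mafa (0.07 ± 0.16) were not called. Among 14 genes of immature beta cells or normally silent in them, 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0909). Aldh1a3 rose (1.72 ± 0.32), while hexokinase Hk1 (-0.56 ± 0.14) and the repressor Rest (-0.96 ± 0.25) fell. The hormones of other islet cells, Gcg (-0.22 ± 0.24), Sst (-0.22 ± 0.14) and Ppy (-0.55 ± 0.37), were not called. edgeR called 0 of 12 alpha cell genes (0 at unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom), 0 of 9 delta and PP cell genes (3, 1 and 0) and 0 of 17 acinar genes (0, 0 and 0). Each count was also 0 when adjusted over the list alone (camera adjusted p = 0.404, 0.324 and 0.300).

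Some genes listed for non-endocrine cells were lower at 1 DPA, in cells that were not identified. In the macrophage list 11 of 14 genes fell, 13 when adjusted over the list alone (camera adjusted p = 0.0131), such as Cx3cr1 (log2 fold change -0.98 ± 0.20), Ms4a7 (-1.21 ± 0.25) and C1qa (-1.21 ± 0.29). CTRL replicate 3 scored 2.82 for macrophages, within the 1 DPA range, and 4.70 for stroma, below it. In the endothelial list 7 of 12 fell, 9 when adjusted over the list alone (camera adjusted p = 0.0137), such as Kdr (-0.70 ± 0.10), Flt1 (-0.41 ± 0.09) and Esm1 (-0.82 ± 0.14). Among 14 phagocyte lipid and efferocytosis genes 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0350, adjusted p = 0.769 with an estimated correlation for each of these lists), such as Lpl (-0.60 ± 0.09), Axl (-0.91 ± 0.25) and Timd4 (-4.43 ± 1.28). In the duct list 3 of 10 fell, 2 when adjusted over the list alone (camera adjusted p = 0.0909). These were Epcam (-0.59 ± 0.07), Bicc1 (-0.71 ± 0.09) and Sox9 (-0.68 ± 0.25). Of 14 stellate cell, fibroblast and pericyte genes 3 fell, 0 when adjusted over the list alone (camera adjusted p = 0.0713). These were Sparc (-0.67 ± 0.21), Cspg4 (-0.47 ± 0.15) and Rgs5 (-0.30 ± 0.10). In the monocyte and neutrophil list 3 of 7 measured genes fell, also when adjusted over the list alone (camera adjusted p = 0.173), such as Plac8 (-3.00 ± 1.00) and Csf3r (-1.33 ± 0.47). Cd4 (-5.30 ± 1.88) was the lower 1 of 3 measured lymphocyte genes, 0 when adjusted over the list alone (camera adjusted p = 0.531). Of 8 Schwann cell genes 1 fell, 1 also when adjusted over the list alone (camera adjusted p = 0.404). The calls of Sox9, Cspg4, Sparc, Rgs5, Plac8, Csf3r and Cd4 ended without CTRL replicate 1 and those of Timd4, Plac8, Csf3r and Cd4 without 1 DPA replicate 1 or 2. Those of Sox9, Plac8 and Cd4 also ended without CTRL replicate 2, Sox9 and Sparc without 1 DPA replicate 1 and Sparc and Rgs5 without 1 DPA replicate 2. Further ended were those of Sox9, Cspg4, Plac8, Csf3r and Cd4 without 1 DPA replicate 3, and Sox9 and Cd4 without 5 DPA replicate 2 (adjusted p 0.0501 to 0.161). With the macrophage covariate Plac8, Csf3r and Cd4 turned to 1.07, 0.26 and 1.37.

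Of 18 genes that p53 activates 10 rose and 1 fell at 1 DPA, also when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.769 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, mm10), rose from 37.4 ± 7.88 to 94.7 ± 8.31 CPM (log2 fold change 1.34 ± 0.25, edgeR adjusted p = 0.00149). The pro-apoptotic Bbc3 (1.44 ± 0.14) and the receptor Eda2r (1.47 ± 0.18) rose too. Of 14 immediate early genes 7 rose, also when adjusted over the list alone (camera adjusted p = 0.0747), such as Egr1 (2.38 ± 0.39) and Junb (2.22 ± 0.37). In the list of unfolded protein and integrated stress responses 10 of 20 genes fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0350, adjusted p = 0.769 with an estimated correlation). Ddit3 (1.88 ± 0.13) and Atf4 (1.19 ± 0.10), transcription factors of the integrated stress response, rose, and Manf (-1.12 ± 0.09), an endoplasmic reticulum stress factor, fell. The NF-kB inhibitors Nfkbia (2.40 ± 0.28) and Tnfaip3 (3.16 ± 0.45) rose and the chemokine Ccl7 (-3.82 ± 0.87) fell. In that inflammatory list 2 of 16 rose and 3 fell, or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.465). Of 16 interferon response genes 9 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0584). Stat2 (-0.49 ± 0.13) and Mx1 (-3.09 ± 0.87) were lower and Irf9 (0.49 ± 0.13) was higher. The calls of Mx1 and Irf9 ended without 1 DPA replicate 2 (adjusted p = 0.0535) and 1 DPA replicate 3 (0.0537).

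Cell cycle genes went both ways at 1 DPA. In the list for G1/S and DNA replication 11 of 24 genes fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0350, adjusted p = 0.769 with an estimated correlation), such as the replicative helicase genes Mcm4 (log2 fold change -0.83 ± 0.12) and Mcm5 (-0.87 ± 0.18) and Dut (-0.46 ± 0.09). In the list for G2/M and mitosis 5 of 26 rose and 3 fell, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.404). Kif20a (1.65 ± 0.27), Nusap1 (1.06 ± 0.25) and Ube2c (1.18 ± 0.28) rose. The proliferation marker Mki67 fell (-0.96 ± 0.35, edgeR adjusted p = 0.0415), a call that ended without CTRL replicate 1 or 3, 1 DPA replicate 2 or 3 or 3 DPA replicate 2 or 3 (adjusted p 0.0519 to 0.113). Top2a (-0.77 ± 0.33) was not called. Of 15 genes for D cyclins, their kinases and inhibitors 5 fell and 3 rose, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.173). Ccnd1, cyclin D1 (-0.80 ± 0.09), and menin, Men1 (-0.50 ± 0.07), fell and the retinoblastoma gene Rb1 (0.47 ± 0.06) rose.

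Growth factor genes also went both ways, 5 of 19 measured rising and 7 falling at 1 DPA, also when adjusted over the list alone (camera adjusted p = 0.929, median -0.08, mean 0.16). Beside Igf2, the receptors Egfr (log2 fold change 1.75 ± 0.13) and Igf1r (1.57 ± 0.13) rose. In the prolactin and serotonin list 4 of 11 measured genes rose and 2 fell, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.640, median -0.29, mean 0.15). Tph2 (1.53 ± 0.34), Stat5b (0.34 ± 0.08) and Socs2 (0.76 ± 0.20) rose. The Socs2 call ended without 1 DPA replicate 3 (adjusted p = 0.0630). Among 16 cholesterol synthesis genes 10 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.769 with an estimated correlation), Insig1 (-0.76 ± 0.09) among them. In the ribosomal protein list 11 of 20 fell and 1 rose, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.769 with an estimated correlation), such as Rplp0 (-0.49 ± 0.06) and Rps4x (-0.34 ± 0.06). Oxidative phosphorylation genes split, 8 of 20 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.640). Uqcrc2 (0.59 ± 0.06) rose and Ndufa4 (-0.91 ± 0.08) and Atp5g1 (-0.47 ± 0.07) fell, and the list's median of 0.07 became -0.06 without the 50 most abundant genes. The phagocyte call ended without CTRL replicate 1 or 2 or 1 DPA replicate 1 or 2 (adjusted p 0.0521 to 0.131) and that of G1/S genes without CTRL replicate 1 or 1 DPA replicate 2 or 3 (0.0523 to 0.0955). That of stress response genes ended without CTRL replicate 1 or 2, 1 DPA replicate 3 or 3 DPA replicate 2 (0.0523 to 0.0978) and that of ribosomal genes without 1 DPA replicate 2 (0.0537). With the macrophage covariate the calls of the endothelial (adjusted p = 0.149), phagocyte (0.878), G1/S (0.129), stress response (0.403) and ribosomal lists (0.425) ended. The macrophage call (0.692) ended by design. With the stromal score the calls of the phagocyte (0.202), G1/S, stress response and ribosomal lists (0.0951 each) ended, and fry did not call the first 2 (0.0703 each).

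At 3 DPA 8 of 14 immediate early genes rose (camera adjusted p = 4.40e-16, adjusted p = 0.226 with an estimated correlation). Egr4, a transcription factor of that class (chromosome 6, 85511121 to 85513589, mm10), went from 0.152 ± 0.0311 CPM in CTRL to 792 ± 412 at 3 DPA (n = 3 each; log2 fold change 12.32 ± 0.54, edgeR adjusted p = 2.35e-06). Egr1 went from 98.5 ± 52.6 to 5886 ± 2003 CPM (5.90 ± 0.46, adjusted p = 3.85e-05). Cdkn1a rose 7.64-fold to 286 ± 99.6 CPM (2.93 ± 0.27, adjusted p = 7.64e-05) and Igf2 29.6-fold to 376 ± 146 CPM (4.89 ± 0.38, adjusted p = 3.69e-05). The neutrophil-attracting chemokines Cxcl2 (6.30 ± 0.73) and Cxcl1 (5.55 ± 0.70) rose too. In all, 2182 genes changed, 1772 higher and 410 lower. Without 3 DPA replicate 1 the count was 1372, and the lower count was 738 without CTRL replicate 1, 995 without 1 DPA replicate 3, 244 without 3 DPA replicate 1 and 180 without 3 DPA replicate 3. With the acinar covariate 1372 genes changed, 172 lower, and 18 of 47 named calls ended.

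Other large rises at 3 DPA were Sec1 (log2 fold change 9.05 ± 1.04), Gys2 (8.77 ± 0.80) and Igf2os (8.21 ± 0.52). Hormad2 and Hist1h2ad were at least 169-fold and 106-fold higher against the floor. Hbegf fell from 47.2 ± 27.2 to 11.6 ± 1.52 CPM (-2.02 ± 0.41, edgeR adjusted p = 0.00887), with 10.2 and 10.7 at 1 and 5 DPA. Whether reads of the toxin receptor transgene, a form of Hbegf, were counted there was not tested. Lower too were mt-Atp8 (-1.05 ± 0.22), Slc23a4 (-1.01 ± 0.21), Enpp2 (-0.94 ± 0.15), Prlr (-0.90 ± 0.16) and Aldh1l2 (-0.95 ± 0.23). The Aldh1l2 call ended without 3 DPA replicate 1 or 3 (adjusted p 0.0567 and 0.0664).

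Of 18 beta cell genes 5 fell at 3 DPA, 8 when adjusted over the list alone (camera adjusted p = 0.000254, adjusted p = 0.986 with an estimated correlation). Glp1r (log2 fold change -0.52 ± 0.11), the zinc transporter Slc30a8 (-0.46 ± 0.11) and Slc2a2 (-0.49 ± 0.12) fell, the calls of Slc30a8 and Slc2a2 ending without 3 DPA replicate 3 (edgeR adjusted p = 0.0548 and 0.0687). Ins1 (-0.34 ± 0.18), Ins2 (-0.08 ± 0.16), Pdx1 (-0.34 ± 0.11) and Mafa (-0.14 ± 0.16) were not called. The somatostatin gene Sst rose (0.56 ± 0.14), 1 of 9 delta and PP cell genes, 5 when adjusted over the list alone (camera adjusted p = 0.268). Pou3f4 (0.97 ± 0.27) was the 1 of 12 alpha cell genes that rose, also when adjusted over the list alone (camera adjusted p = 0.0662). The Sst call ended without CTRL replicate 1 or 3 DPA replicate 1 or 3 (adjusted p 0.0855 to 0.0896) and that of Pou3f4 without CTRL replicate 1 or 2, 1 DPA replicate 2, any 3 DPA library or 5 DPA replicate 3 (adjusted p 0.0507 to 0.124). Gcg (0.59 ± 0.24) and Ppy (-0.06 ± 0.36) were not called. The acinar list had a median of -2.12 and camera called it lower (adjusted p = 0.000146, adjusted p = 0.986 with an estimated correlation). Among its 17 genes edgeR called 0, 0 also when adjusted over the list alone, 10 at unadjusted p under 0.05, 8 with DESeq2 and 0 with limma-voom.

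The p53 targets rose as a list at 3 DPA (camera adjusted p = 7.17e-12, adjusted p = 0.226 with an estimated correlation), 9 of 18 higher, 11 when adjusted over the list alone. Bax, a pro-apoptotic gene, rose (log2 fold change 1.65 ± 0.14), as did Aen (1.31 ± 0.09). Of the 14 immediate early genes 10 were higher when adjusted over the list alone. Jun (2.77 ± 0.23) and Nr4a1 (5.55 ± 0.44) rose. In the inflammatory list 6 of 16 rose, also when adjusted over the list alone (camera adjusted p = 0.00283, adjusted p = 0.986 with an estimated correlation), such as Nfkbia (2.07 ± 0.28). The stress response list had 5 of 20 genes higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.559, median -0.03, mean 0.39). Ddit3 (1.41 ± 0.13), Ppp1r15a (1.17 ± 0.15) and Atf4 (0.59 ± 0.10) rose. Of 16 cholesterol synthesis genes 2 fell, 3 when adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.986 with an estimated correlation), a list call that ended without CTRL replicate 2 (adjusted p = 0.0964) and with the acinar covariate (0.197), as did that of the acinar list with this covariate (0.566). fry did not call the cholesterol and beta cell lists (0.103 each), the acinar list (0.181) or the inflammatory list (0.0858). Insig1 (-0.44 ± 0.09) fell. Growth factor genes numbered 3 of 19 higher and 3 lower, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.559), with Btc, betacellulin (2.12 ± 0.37), higher. In the prolactin and serotonin list Tph2 rose (2.25 ± 0.34) and Prlr fell, 1 of 11 each way, or 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.108, median -0.24, mean 0.02).

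The proliferation genes Mki67 (log2 fold change -0.36 ± 0.34) and Top2a (-0.01 ± 0.33) were not called at 3 DPA. In the G2/M list 4 of 26 rose, also when adjusted over the list alone (camera adjusted p = 0.739). Nusap1 (1.93 ± 0.25), Kif20a (1.22 ± 0.27) and Birc5, survivin (1.45 ± 0.33), were the 3 of smallest p. The calls of Kif20a and Birc5 ended without CTRL replicate 2 or 3 DPA replicate 1 (edgeR adjusted p 0.0542 to 0.0700). In the G1/S list 2 of 24 rose, Cdc6 (1.17 ± 0.30) and Slbp (0.25 ± 0.07), and 0 when adjusted over the list alone (camera adjusted p = 0.816). The Cdc6 call ended without CTRL replicate 2 or 3 or 3 DPA replicate 1 or 2 (adjusted p 0.0589 to 0.0980). Cdkn1a was the 1 of 15 D cyclin, kinase and inhibitor genes that rose, also when adjusted over the list alone (camera adjusted p = 0.971, median -0.02, mean 0.08). Ngfr, the p75 neurotrophin receptor (1.27 ± 0.21), was the 1 of 8 Schwann cell genes that rose (camera adjusted p = 0.453) and Timp1 (2.11 ± 0.49) the 1 of 14 stromal genes (0.516), both also when adjusted over the list alone. The Timp1 call ended without CTRL replicate 1 or 3 DPA replicate 1 (adjusted p 0.0617 and 0.0755). Ribosomal protein genes had 3 of 20 higher, 5 when adjusted over the list alone (camera adjusted p = 0.243): Rpl18 rose 3.36-fold (1.75 ± 0.29), and Rps14 (0.28 ± 0.08) and Rps6 (0.22 ± 0.06) rose. Rpl18 (chromosome 7, 45715457 to 45720836) lies beyond the 3' end of the clock gene Dbp (45705088 to 45710203) on the same strand (mm10). Oxidative phosphorylation genes had 3 of 20 higher, also when adjusted over the list alone (camera adjusted p = 0.559), Uqcrc2 (0.40 ± 0.06), Cox4i1 (0.23 ± 0.06) and Atp5b (0.25 ± 0.07). Small changes lost their call in 6 to 11 of the 12 fits without 1 library (adjusted p up to 0.307). Those of Cox4i1, Rps14 and Rps6 ended without any CTRL library, 1 DPA replicate 3 or 3 DPA replicate 1 or 3, Rps6 also without 5 DPA replicate 2. Atp5b lost its call in all but those without 1 DPA replicate 2 or 3 DPA replicate 2, and Slbp in all but that without 5 DPA replicate 1.

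edgeR called 0 members at 3 DPA in 8 further lists, also 0 when adjusted over the list alone. For the immature or silenced beta cell genes (0 of 14) the counts at unadjusted p under 0.05, with DESeq2 and with limma-voom were 3, 2 and 0 (camera adjusted p = 0.600). In that order they were 2, 1 and 1 for duct genes (0 of 10; 0.960), for endothelial genes (0 of 12) 0, 0 and 0 (0.658), and for macrophage genes (0 of 14) 1, 1 and 1 (0.960). For phagocyte genes (0 of 14) they were 4, 2 and 2 (camera adjusted p = 0.816) and for monocyte and neutrophil genes (0 of 7) 1, 0 and 0 (0.971). The counts were for lymphocyte genes (0 of 3) 0, 0 and 0 (0.791), and for interferon response genes (0 of 16) 1, 0 and 0 (0.911).

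At 5 DPA 21 of 26 mitosis genes were higher (camera adjusted p = 7.36e-18, adjusted p = 0.240 with an estimated correlation). Top2a, the topoisomerase of replicating cells (chromosome 11, 98992943 to 99024189, mm10), rose from 8.39 ± 2.39 CPM in CTRL to 23.9 ± 10.7 (n = 3 each; log2 fold change 1.51 ± 0.33, edgeR adjusted p = 0.0207). Mki67 went from 9.71 ± 2.23 to 22.4 ± 9.86 CPM without passing the threshold (1.21 ± 0.34, adjusted p = 0.0558). Cdkn1a was 3.51-fold higher at 131 ± 17.9 CPM (1.81 ± 0.26, adjusted p = 0.00413), Egr1 stood at 2223 ± 500 CPM (4.50 ± 0.43, adjusted p = 0.000627) and Igf2 13.4-fold above CTRL at 170 ± 16.8 CPM (3.74 ± 0.36, adjusted p = 0.000640). Glp1r fell (-0.69 ± 0.11, adjusted p = 0.00474). In all, 1477 genes changed, 1016 higher and 461 lower (68.8% higher), or 1095 and 289 (79.1% higher) without the 50 most abundant genes in the library size. The count was 462 without 5 DPA replicate 1, 823 without 5 DPA replicate 3, 726 without CTRL replicate 2 and 745 without CTRL replicate 3. The lower count alone was 807, 243 and 136 without CTRL replicates 1, 2 and 3, 765 without 1 DPA replicate 3, 307 without 3 DPA replicate 3 and 57, 249 and 192 without 5 DPA replicates 1, 2 and 3. The Top2a call ended without 5 DPA replicate 1 or CTRL replicate 2 or 3 (adjusted p 0.0648 to 0.0793).

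The 26 mitosis genes, the G2/M list, had a median log2 fold change of 1.41 at 5 DPA, and 25 were higher when adjusted over the list alone. Nusap1 (1.65 ± 0.25), the cytokinesis gene Prc1 (1.38 ± 0.23) and Ube2c (1.63 ± 0.28) had the smallest p. The number called was 5 without 5 DPA replicate 1 (median 1.01), 7 and 8 without CTRL replicates 2 and 3 (1.27 and 1.34), 2 with only the 2 groups in the fit (1.40), and 0 with the macrophage or stromal score as a covariate (1.31 and 1.08). Camera then still called the list (adjusted p = 3.67e-14 and 4.67e-11) and fry did not (0.168 and 0.213), and camera called it in all 12 fits without 1 library. In the G1/S list 15 of 24 rose, 20 when adjusted over the list alone (camera adjusted p = 3.65e-12, adjusted p = 0.240 with an estimated correlation), such as Mcm5 (1.15 ± 0.18), the replication clamp gene Pcna (0.65 ± 0.10) and Cdc6 (1.88 ± 0.30). Of the D cyclin, kinase and inhibitor genes Cdkn1a was the 1 of 15 that rose, also when adjusted over the list alone (camera adjusted p = 0.996). The list's median of -0.02 was above 0 without the 50 most abundant genes.

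Some stromal, macrophage and glial genes were higher at 5 DPA, where stromal scores were 7.32, 6.69 and 6.82 against 6.46, 6.18 and 4.70 in CTRL. In the stellate cell, fibroblast and pericyte list 3 of 14 rose, 10 when adjusted over the list alone (camera adjusted p = 3.03e-06, adjusted p = 0.372 with an estimated correlation). These were Rgs5 (log2 fold change 0.53 ± 0.10), periostin, Postn (1.60 ± 0.42), and the PDGF receptor Pdgfrb (0.74 ± 0.20). In the macrophage list 3 of 14 rose, 4 when adjusted over the list alone (camera adjusted p = 2.83e-06, adjusted p = 0.389 with an estimated correlation). These were Ms4a7 (1.46 ± 0.25), Cx3cr1 (1.04 ± 0.20) and Itgax (1.82 ± 0.35). Among phagocyte genes 3 of 14 rose, 5 when adjusted over the list alone (camera adjusted p = 0.000812, adjusted p = 0.396 with an estimated correlation). These were the lipid receptor Trem2 (1.97 ± 0.30), Lgals3 (2.19 ± 0.57) and Axl (0.92 ± 0.25). In the Schwann cell list 5 of 8 rose, 6 when adjusted over the list alone (camera adjusted p = 5.70e-06, adjusted p = 0.240 with an estimated correlation), such as Ngfr (1.97 ± 0.22), Foxd3 (1.17 ± 0.23) and the intermediate filament gene Gfap (1.26 ± 0.25). Chil3 (3.29 ± 0.92) was the 1 of 7 monocyte and neutrophil genes that rose, also when adjusted over the list alone (camera adjusted p = 0.102). The calls of Postn, Pdgfrb, Lgals3, Axl and Chil3 ended in 10 or 11 of the 12 fits without 1 library (edgeR adjusted p 0.0512 to 0.169). All were kept without CTRL replicate 1, Postn and Axl also without CTRL replicate 3 and Chil3 without 3 DPA replicate 3. That of Cx3cr1 ended without CTRL replicate 2 (0.0558), that of Itgax without CTRL replicate 2 or 5 DPA replicate 1 (0.0535 and 0.0617) and that of Gfap without 5 DPA replicate 1 (0.0557). With the stromal covariate 47 of 55 named calls at 5 DPA ended, and with the macrophage score 42. The stromal list call ended with either score (camera adjusted p = 0.444 and 0.227, in that order). So did those of the macrophage list with the stromal score (0.462) and the phagocyte list with the macrophage score (0.861).

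Of 18 beta cell genes 7 fell at 5 DPA, 8 when adjusted over the list alone (camera adjusted p = 2.48e-08, adjusted p = 0.334 with an estimated correlation), such as the channel gene Trpm5 (log2 fold change -0.72 ± 0.12), urocortin 3, Ucn3 (-0.60 ± 0.12), Pdx1 (-0.45 ± 0.11, edgeR adjusted p = 0.0327) and Slc2a2 (-0.42 ± 0.12, adjusted p = 0.0451). The Ucn3 call ended without 5 DPA replicate 1 (adjusted p = 0.0673). That of Pdx1 ended without CTRL replicate 3, 1 DPA replicate 2, 3 DPA replicate 3 or 5 DPA replicate 1 or 3 (0.0502 to 0.140) and that of Slc2a2 without those or CTRL replicate 2 (0.0620 to 0.182). Ins1 (-0.10 ± 0.18), Ins2 (-0.16 ± 0.16), Mafa (-0.32 ± 0.16), Gcg (0.09 ± 0.24), Sst (0.42 ± 0.14) and Ppy (0.19 ± 0.36) were not called. By the naming rule the largest falls were those of Hbegf (-2.14 ± 0.41), Slitrk1 (-1.23 ± 0.34), Adgrv1 (-1.05 ± 0.13), the potassium channel gene Kcng3 (-0.97 ± 0.21), endothelin 2, Edn2 (-0.86 ± 0.24), and Lingo3 (-0.84 ± 0.19). Slitrk1 and Edn2 lost their call in 11 of the 12 fits without 1 library (adjusted p 0.0510 to 0.188, kept only without CTRL replicate 1 for Slitrk1 and without CTRL replicate 2 for Edn2). Hbegf lost it without 5 DPA replicate 1 or 3 (0.0529 and 0.0699), Kcng3 without CTRL replicate 3 or 5 DPA replicate 1 (0.0566 and 0.0752), and Lingo3 without CTRL replicate 3 or 5 DPA replicate 1 or 2 (0.0524 to 0.0975). The largest rises by this rule were Egr4 (10.42 ± 0.52), Igf2os (7.03 ± 0.51) and Sec1 (6.99 ± 1.04), with Hormad2 and Hist1h2ad at least 52.4-fold and 16.5-fold higher against the floor and Mc1r at a ratio of 144 (95% interval 25.4 to 5716).

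Of 18 p53 targets 7 rose at 5 DPA, 8 when adjusted over the list alone (camera adjusted p = 5.70e-06, adjusted p = 0.240 with an estimated correlation), such as Aen (log2 fold change 0.63 ± 0.09) and Bax (0.85 ± 0.14). Of 14 immediate early genes 6 rose, 7 when adjusted over the list alone (camera adjusted p = 2.47e-11, adjusted p = 0.240 with an estimated correlation), such as Nr4a1 (3.54 ± 0.40) and Jun (1.69 ± 0.22). In the inflammatory list 4 of 16 rose, also when adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.396 with an estimated correlation), a list call that ended with the stromal covariate (0.888). Cxcl2 (5.17 ± 0.71), Cxcl1 (4.11 ± 0.67) and Cxcl10 (3.10 ± 0.66) had the smallest p. The stress response list had 4 of 20 higher, also when adjusted over the list alone (camera adjusted p = 0.508), such as Ddit3 (0.74 ± 0.13), Atf3 (3.93 ± 0.77) and Atf4 (0.40 ± 0.10). Cholesterol synthesis genes were lower (camera adjusted p = 4.66e-08, adjusted p = 0.240 with an estimated correlation), 3 of 16 falling, 9 when adjusted over the list alone, Insig1 (-0.57 ± 0.09) among them. Growth factor genes numbered 2 of 19 higher and 2 lower, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.126), with Btc at 2.16 ± 0.37. Tph2 (1.60 ± 0.34) was the 1 of 11 prolactin and serotonin genes that rose, also when adjusted over the list alone (camera adjusted p = 0.351, median -0.19, mean 0.21). Calls ended without CTRL replicate 2 or 5 DPA replicate 1 for Atf3 (edgeR adjusted p 0.0613 and 0.0622), Tph2 (0.0629 and 0.0696) and Cxcl10, which also lost its call without 5 DPA replicate 2 or 3 (0.0555 to 0.0730). That of Atf4 ended without CTRL replicate 1 or 3, 3 DPA replicate 3 or any 5 DPA library (0.0502 to 0.111).

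Camera called 3 lists at 5 DPA in which edgeR called 0 members, also 0 when adjusted over the list alone. The immature or silenced beta cell genes (0 of 14; 6 at unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom) were higher (camera adjusted p = 0.0127, adjusted p = 0.372 with an estimated correlation). That call ended without CTRL replicate 3 or 5 DPA replicate 1 (adjusted p = 0.0574 and 0.0889) and with the macrophage covariate (0.698). The interferon response genes (0 of 16; 4, 3 and 0) were higher (camera adjusted p = 0.0127, adjusted p = 0.620 with an estimated correlation). The interferon call ended without CTRL replicate 3 or 5 DPA replicate 3 (adjusted p = 0.545 and 0.321) and turned lower with the macrophage covariate (6.26e-06), and fry did not call it (0.221). The acinar genes (0 of 17; 0, 0 and 0) were lower (camera adjusted p = 0.00502, adjusted p = 0.620 with an estimated correlation), a call that ended without CTRL replicate 2 (adjusted p = 0.203), with the acinar covariate (0.434) and with fry (0.364). edgeR also called 0 of 12 alpha cell genes (0 at unadjusted p under 0.05, 0 with DESeq2, 0 with limma-voom), 0 of 9 delta and PP cell genes (3, 1 and 0) and 0 of 10 duct genes (1, 0 and 0). It called 0 of 3 lymphocyte genes (1, 1 and 0), 0 of 20 oxidative phosphorylation genes (3, 0 and 0), 0 of 20 ribosomal protein genes (2, 0 and 0) and 0 of 12 endothelial genes (3, 2 and 0). For these 7 lists, in the order given, the camera adjusted p was 0.661, 0.0954, 0.998, 0.474, 0.804, 0.383 and 0.179. Adjusted over the list alone 2 endothelial genes were higher and 1 lymphocyte gene lower, and 0 genes of the other 5 lists.

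**Figure D1:**
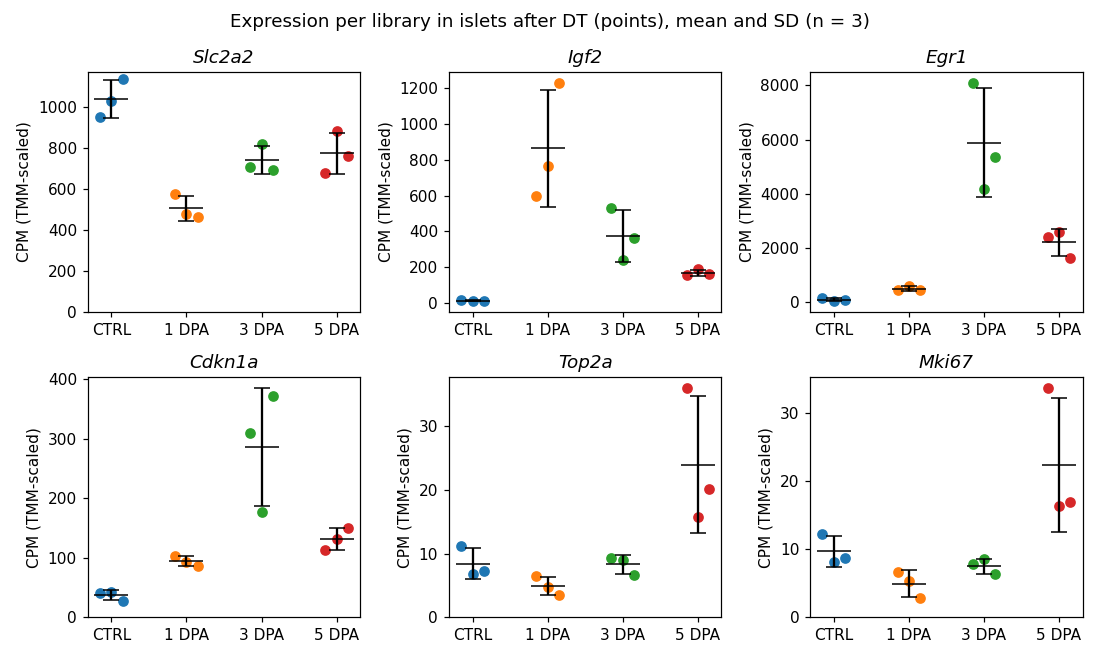
Expression in CPM of Slc2a2, Igf2, Egr1, Cdkn1a, Top2a and Mki67 in each library of the 4 groups, with the mean and SD of the 3 libraries. Slc2a2 is lowest at 1 DPA (507 ± 60.7 CPM), Igf2 highest at 1 DPA (865 ± 328), Egr1 and Cdkn1a highest at 3 DPA (5886 ± 2003 and 286 ± 99.6), and Top2a and Mki67 highest at 5 DPA (23.9 ± 10.7 and 22.4 ± 9.86).

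Between 1 and 3 DPA the chemokine gene Cxcl2 went from 0.307 ± 0.132 to 36.9 ± 17.8 CPM (n = 3 each; log2 fold change 6.91 ± 0.78, edgeR adjusted p = 0.000102), and Cxcl10 (4.96 ± 0.72), Cxcl1 (4.86 ± 0.67) and Egr4 (5.18 ± 0.36) rose as well. Cyp26b1, a retinoic acid hydroxylase, fell from 29.2 ± 24.6 to 0.848 ± 0.286 CPM (-5.10 ± 0.95, adjusted p = 0.00211). Also lower at 3 DPA were Diras2 (-3.85 ± 0.26), Hhipl2 (-3.10 ± 0.21) and the tight junction gene Cldn15 (-3.06 ± 0.45). Slc2a2 (0.54 ± 0.12), Ins1 (0.47 ± 0.18), Gcg (0.81 ± 0.24), Sst (0.78 ± 0.14) and Cdkn1a (1.59 ± 0.25) were higher at 3 than at 1 DPA. The call of Ins1 ended without CTRL replicate 1 or 2, 1 DPA replicate 2 or 3, 3 DPA replicate 2 or 3 or 5 DPA replicate 1 or 3 (adjusted p 0.0509 to 0.137) and that of Gcg without 1 DPA replicate 1 or 3 DPA replicate 3 (0.0601 and 0.0704). In all, 7805 genes differed, 3534 higher and 4271 lower at 3 DPA (45.3% higher), or 4927 and 3316 (59.8% higher) without the 50 most abundant genes, where the median of all genes moved from 0.04 to 0.15.

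All 14 macrophage genes and 19 of 20 ribosomal protein genes were higher at 3 than at 1 DPA, both also when adjusted over the list alone (camera adjusted p = 0.000203, adjusted p = 0.575 with an estimated correlation, for each). Higher too were 10 of 14 stromal genes, 11 when adjusted over the list alone (camera adjusted p = 0.00276). So were 9 of 12 endothelial genes, 10 when adjusted over the list alone (0.00528), and 7 of 14 phagocyte genes with 1 lower, or 10 and 1 when adjusted over the list alone (0.00276; adjusted p = 0.575 with an estimated correlation for each of these). In the stress response list 10 of 20 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.00124), and 5 of 14 immediate early genes rose, 8 when adjusted over the list alone (0.00124; adjusted p = 0.575 with an estimated correlation for both). G1/S genes numbered 10 of 24 higher, also when adjusted over the list alone (camera adjusted p = 0.00295). Inflammatory genes numbered 7 of 16 higher and 1 lower, or 8 and 1 when adjusted over the list alone (0.00329; adjusted p = 0.575 with an estimated correlation for both lists). Interferon response genes numbered 4 of 16 higher, 3 when adjusted over the list alone (0.0187, adjusted p = 0.689 with an estimated correlation). Among islet lists, 9 of 14 immature or silenced beta cell genes rose, 10 with 1 lower when adjusted over the list alone (camera adjusted p = 0.00802), and 5 of 12 alpha cell genes, 9 when adjusted over the list alone (0.0138; adjusted p = 0.575 with an estimated correlation for both). Higher too, also when adjusted over the list alone, were 4 of 9 delta and PP cell genes (0.0214) and 5 of 10 duct genes (0.0442; adjusted p = 0.575 with an estimated correlation for both). The duct call also ended without 1 DPA replicate 2 or 3 or 3 DPA replicate 1 (0.0519 to 0.115), and fry did not call the interferon list (0.109). Of these 14 lists only the alpha cell and G1/S lists kept their call and direction with the macrophage covariate (0.0593 to 0.847 for those not called). With the stromal score the calls of the immature beta cell, duct, endothelial, stromal, phagocyte, immediate early, inflammatory and interferon lists ended (0.0584 to 0.768).

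The other 12 lists were not called between 1 and 3 DPA. Beta cell genes numbered 6 higher and 3 lower of 18 (camera adjusted p = 0.272), p53 targets 6 and 2 of 18 (0.300), and growth factor genes 7 and 5 of 19 (0.655). The numbers were, for oxidative phosphorylation genes 6 and 6 of 20 (0.222), cholesterol synthesis genes 7 and 1 of 16 (0.118), D cyclin, kinase and inhibitor genes 5 and 2 of 15 (0.0658), and prolactin and serotonin genes 1 and 3 of 11 (0.466). Each was the same when adjusted over the list alone. The prolactin list's median of -0.11 was above 0 without the 50 most abundant genes. G2/M genes numbered 3 of 26 higher, 2 when adjusted over the list alone (camera adjusted p = 0.128), Schwann cell genes 3 of 8 (0.0658) and monocyte and neutrophil genes 2 of 7 (0.0688), both also when adjusted over the list alone. edgeR called 0 of 17 acinar genes (0 at unadjusted p under 0.05, 0 with DESeq2, 0 with limma-voom; camera adjusted p = 0.222) and 0 of 3 lymphocyte genes (0, 2 and 0; 0.546), 0 also when adjusted over the list alone.

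Between 3 and 5 DPA 11 of 26 mitosis genes (the G2/M list) rose (camera adjusted p = 2.44e-22, adjusted p = 0.389 with an estimated correlation). The kinase genes Cdk1 (2.08 ± 0.766 to 6.76 ± 2.37 CPM, n = 3 each; log2 fold change 1.70 ± 0.34, edgeR adjusted p = 0.0247) and Pbk (1.75 ± 0.35) were higher at 5 DPA. So were the spindle gene Ckap2 (1.74 ± 0.29), Top2a (1.52 ± 0.33, adjusted p = 0.0366) and Mki67 (1.57 ± 0.35, adjusted p = 0.0400), and Adam33 (1.80 ± 0.40). Cdkn1a (-1.12 ± 0.25), Hist1h2ad (-2.67 ± 0.51), Hist1h4c (-2.37 ± 0.37), the plasmin inhibitor gene Serpinf2 (-2.31 ± 0.54) and Rsph6a (-2.27 ± 0.40) were lower. In all, 547 genes differed, 122 higher and 425 lower. The count was 31, 33 and 70 without 5 DPA replicates 2, 1 and 3, and 48, 288 and 186 without 3 DPA replicates 1, 2 and 3. It was 314 and 1018 without CTRL replicates 2 and 3 and 347 without 1 DPA replicate 2. With the replicate number as a block, which may pair the 3 and 5 DPA libraries, 340 genes differed, 241 lower. It ended the calls of Adam33 (1.74 ± 0.38, edgeR adjusted p = 0.0509), Hist1h2ad (-2.68 ± 0.54, 0.0598), Serpinf2 (-2.31 ± 0.61, 0.105) and Cdkn1a (-1.10 ± 0.27, 0.0921).

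The 8 genes that the rule names for the largest changes between 3 and 5 DPA each lost their call in 3 to 9 of the 12 fits without 1 library. Without 5 DPA replicate 1 all 8 ended, and Adam33, Pbk, Cdk1, Hist1h2ad, Hist1h4c, Serpinf2 and Rsph6a also ended without 5 DPA replicate 2 or 3. Without 3 DPA replicate 1 all 8 ended, without 3 DPA replicate 2 Adam33, Pbk, Cdk1, Hist1h2ad and Serpinf2, and without 3 DPA replicate 3 Adam33, Pbk, Ckap2, Cdk1 and Serpinf2. Adam33, Hist1h2ad and Serpinf2 ended too without 1 DPA replicate 1 or 2, Adam33 without CTRL replicate 2 and Serpinf2 without CTRL replicate 1 (edgeR adjusted p 0.0508 to 0.216). The calls of Top2a and Mki67 ended without CTRL replicate 2, 1 DPA replicate 2 or any 3 or 5 DPA library (0.0579 to 0.154), and that of Cdkn1a in all but the fits without CTRL replicate 3 or 3 DPA replicate 2 (0.0630 to 0.194).

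Of the 26 genes of the G2/M list 23 were higher at 5 than at 3 DPA when adjusted over the list alone. In the G1/S list 8 of 24 were higher, 17 when adjusted over the list alone (camera adjusted p = 1.20e-15, adjusted p = 0.389 with an estimated correlation). Also when adjusted over the list alone, macrophage genes numbered 2 of 14 higher (camera adjusted p = 1.85e-08, adjusted p = 0.450 with an estimated correlation) and stromal genes 1 of 14 (4.36e-05, adjusted p = 0.545 with an estimated correlation). Phagocyte genes numbered 1 of 14, or 4 higher and 1 lower when adjusted over the list alone (0.000344, adjusted p = 0.545 with an estimated correlation). The p53 targets were lower, 5 of 18 falling and 1 rising, or 10 and 1 when adjusted over the list alone (camera adjusted p = 1.66e-06, adjusted p = 0.395 with an estimated correlation), such as Aen (log2 fold change -0.67 ± 0.09) and Bax (-0.80 ± 0.14). Immediate early genes were lower too, 3 of 14 falling, 7 when adjusted over the list alone (camera adjusted p = 2.03e-07, adjusted p = 0.450 with an estimated correlation), such as Nr4a1 (-2.01 ± 0.37) and Jun (-1.08 ± 0.22). The calls of Bax, Nr4a1 and Jun ended without 3 DPA replicate 1 or 3 or any 5 DPA library, and that of Jun also without 1 DPA replicate 2 (edgeR adjusted p 0.0513 to 0.135). The D cyclin list had 1 of 15 lower (camera adjusted p = 0.968), the stress response list 1 of 20 lower, 2 when adjusted over the list alone (0.676), and the oxidative phosphorylation list 1 of 20 lower (0.404), the first and last also when adjusted over the list alone. With the replicate block 1 macrophage gene was higher, and 0 genes of the stromal, D cyclin and oxidative phosphorylation lists were called. Adjusted over the list alone, it left 1 phagocyte gene higher and 0 D cyclin genes lower.

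Camera called 7 lists between 3 and 5 DPA in which edgeR called 0 members. Higher were Schwann cell genes (0 of 8; 6 at unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom; camera adjusted p = 0.000184, adjusted p = 0.450 with an estimated correlation) and endothelial genes (0 of 12; 2, 0 and 0; 0.00508, adjusted p = 0.545 with an estimated correlation). Also higher were acinar genes (0 of 17; 0, 0 and 0; 0.00673, adjusted p = 0.726 with an estimated correlation), monocyte and neutrophil genes (0 of 7; 1, 0 and 0; 0.0311, adjusted p = 0.568 with an estimated correlation) and interferon response genes (0 of 16; 2, 0 and 0; 0.000373, adjusted p = 0.568 with an estimated correlation). Lower were alpha cell genes (0 of 12; 1, 0 and 0; 0.0115, adjusted p = 0.568 with an estimated correlation) and cholesterol synthesis genes (0 of 16; 4, 0 and 0; 0.0205, adjusted p = 0.568 with an estimated correlation). Single libraries ended the calls of the endothelial list (5 DPA replicate 1, adjusted p = 0.0535), the acinar and alpha lists (3 DPA replicate 3 or 5 DPA replicate 3, 0.0760 to 0.197), the interferon list (5 DPA replicate 3, 0.0900). They also ended those of the cholesterol list (3 DPA replicate 2 or 5 DPA replicate 1 or 2, 0.0600 to 0.0784) and the monocyte list (CTRL replicate 2, 1 DPA replicate 1 or 3, 3 DPA replicate 2 or 3 or 5 DPA replicate 3, 0.0539 to 0.328). Adjusted over the list alone 6 Schwann cell genes were higher and 0 genes of the other 6 lists. fry called none of the 14 lists that camera called between 3 and 5 DPA (0.0614 to 0.532). With the macrophage covariate those called were the G1/S, G2/M, Schwann cell, p53 and immediate early lists, and the interferon list in the other direction (0.0919 to 0.917 for the rest). With the stromal score the calls of these 7 lists but the Schwann cell list ended, as did those of the stromal and phagocyte lists (0.0688 to 0.755). The acinar score ended the alpha (0.0818) and monocyte calls (0.207).

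In the other lists edgeR called 0 members between 3 and 5 DPA. These were 0 of 18 beta cell genes (3 at unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom; camera adjusted p = 0.415), 0 of 14 immature or silenced beta cell genes (1, 0 and 0; 0.0745). Others were 0 of 9 delta and PP cell genes (0, 0 and 0; 0.970), 0 of 10 duct genes (1, 1 and 0; 0.874) and 0 of 3 lymphocyte genes (1, 0 and 0; 0.892). The same held for inflammatory genes (0 of 16; 3, 1 and 2; camera adjusted p = 0.668), growth factor genes (0 of 19; 3, 1 and 0; 0.773), prolactin and serotonin genes (0 of 11; 3, 1 and 1; 0.120) and ribosomal protein genes (0 of 20; 3, 0 and 0; 0.332). Adjusted over the list alone 1 duct gene and 1 prolactin and serotonin gene were higher and 1 lymphocyte gene lower, and 0 genes of the other 6 lists. With the replicate block these counts were 0 duct and 2 prolactin and serotonin genes, with 1 beta cell gene lower.

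Higher in both 1 and 3 DPA were 1500 genes and lower in both 242, with 47 going opposite ways. Independent lists of these sizes would share 517 and 91.8. Between 3 and 5 DPA 671 and 213 were shared (104 and 10.9 for independent lists) and 0 went opposite ways in the edgeR calls, and between 1 and 5 DPA 610 and 235 (296 and 103), with 175 opposite. Unchanged groups simulated against the same CTRL libraries shared 0 calls in 20 simulations, where no comparison had over 1 call, so this 0 says little on the counts shared above. Fold changes correlated across genes, which are not independent replicates, at r = 0.729, 0.864 and 0.567 for these pairs (0.492, 0.496 and 0.492 in the simulations), with covariances of 0.969, 0.754 and 0.600 (0.0587, 0.0588 and 0.0585). The 3 controls cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls. Without 5 DPA replicate 1 the genes shared by 3 and 5 DPA were 362 higher and 48 lower, and those shared by 1 and 5 DPA 323 and 38. Without 3 DPA replicate 1, 987 were higher at both 1 and 3 DPA, and 109 were lower without 3 DPA replicate 3.

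**Figure D2:**
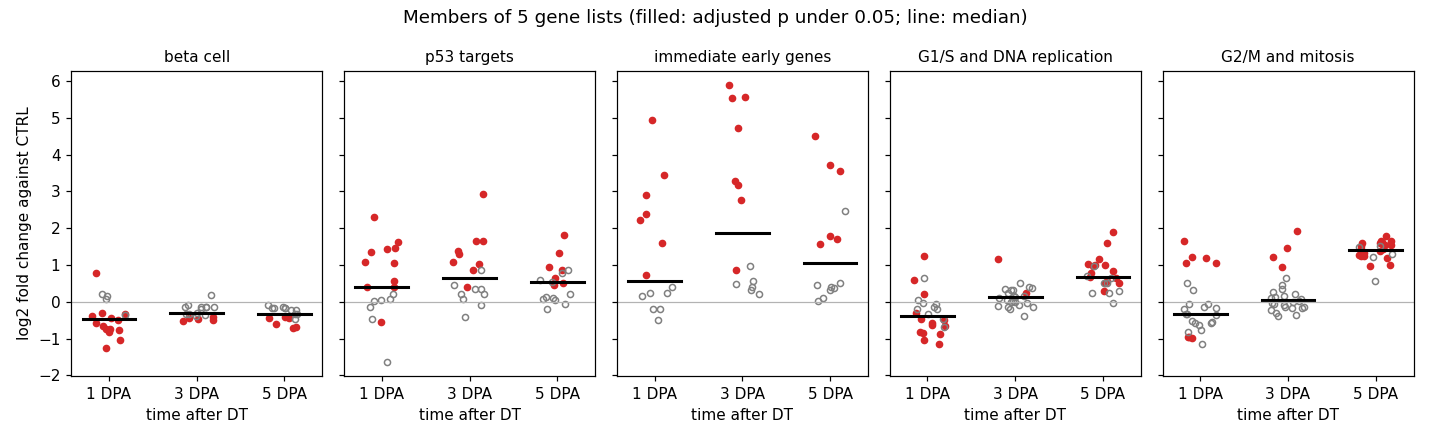
Log2 fold change against CTRL of each member of 5 gene lists at 1, 3 and 5 DPA, filled where the edgeR adjusted p is under 0.05, with a line at the list's median. The G2/M list has 21 of 26 members called higher at 5 DPA (median 1.41), against 5 at 1 DPA and 4 at 3 DPA.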

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

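The tests of depth, of the stromal and macrophage scores and of single 5 DPA libraries on the mitosis genes, and the fits without single libraries between times, were chosen after the result was seen.

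Of 138 named genes 89 differed between 3 and 1 DPA by edgeR's test of that difference, 66 higher and 23 lower at 3 DPA (adjusted p 1.75e-06 to 0.0482), which brought each of them here. In log2 fold change, those higher at 3 DPA were Cxcl2 (6.91), Egr4 (5.18), Cxcl10 (4.96), Cxcl1 (4.86), Chil3 (4.03), Ccl7 (3.96), Hist1h4c (3.72), Egr1 (3.52), Atf3 (3.35), Sec1 (3.03), Lgals3 (2.91) and Btc (2.59). Next came Itgax (2.19), Jun (2.03), Serpinf2 (1.80), Ngfr (1.61), Postn (1.60), Cdkn1a (1.59), Ms4a7 (1.58), Trem2 (1.38), Gys2 (1.31), Sox9 (1.31), Pou3f4 (1.19) and Axl (1.08). Next came C1qa (1.06), Cx3cr1 (1.06), Rest (1.06), Mcm5 (1.01), Manf (1.00), Hk1 (0.98), Ccnd1 (0.94), Ndufa4 (0.87), Nusap1 (0.86), Lpl (0.86), Lingo3 (0.83) and Sparc (0.82). Next came Gcg (0.81), Edn2 (0.81), Sst (0.78), Gfap (0.74), Mcm4 (0.71), Pdgfrb (0.70), Esm1 (0.70), Epcam (0.60), Cspg4 (0.60), Rplp0 (0.60) and Bax (0.57). Next came Slc2a2 (0.54), Bicc1 (0.52), Kdr (0.52), Atp5g1 (0.48), Ins1 (0.47), Pcna (0.47), Rps14 (0.46), Stat2 (0.46), Flt1 (0.43) and Rps4x (0.42). Next came Rgs5 (0.41), Enpp2 (0.41), Ucn3 (0.38), Dut (0.37), Cox4i1 (0.33), Trpm5 (0.33), Insig1 (0.32), Rps6 (0.30) and Men1 (0.28). Lower at 3 than at 1 DPA were Cyp26b1 (-5.10), Diras2 (-3.85), Hhipl2 (-3.10), Cldn15 (-3.06), Hist1h2ad (-1.72), Amhr2 (-1.71), Igf1r (-1.61), Egfr (-1.48), Igf2os (-1.36), Tnfaip3 (-1.29), Mc1r (-1.24) and Socs2 (-1.24). Further lower were Igf2 (-1.20), Bbc3 (-1.08), Aen (-1.002), Kcng3 (-0.69), Prlr (-0.60), Atf4 (-0.59), Stat5b (-0.57), Ddit3 (-0.46), Ppp1r15a (-0.46), Rb1 (-0.41) and Uqcrc2 (-0.19). The calls of 70 of these 89 genes were kept in all 12 fits without 1 library, and 19 ended in some (adjusted p 0.0502 to 0.178).

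Between 5 and 3 DPA 30 named genes differed, 15 each way (edgeR adjusted p 0.00494 to 0.0491). Higher at 5 DPA were Adam33 (1.80), Pbk (1.75), Ckap2 (1.74), Cdk1 (1.70), Mki67 (1.57), Top2a (1.52), Trem2 (1.27), Ms4a7 (1.09), Mcm5 (1.01), Cx3cr1 (0.95), Prc1 (0.94) and Enpp2 (0.70). Higher too were Mcm4 (0.63), Pcna (0.49) and Rgs5 (0.42). Lower at 5 DPA were Hist1h2ad (-2.67), Hist1h4c (-2.37), Serpinf2 (-2.31), Rsph6a (-2.27), Gys2 (-2.27), Nr4a1 (-2.01), Egr4 (-1.90), Hormad2 (-1.67), Cdkn1a (-1.12), Jun (-1.08), Bax (-0.80) and Eda2r (-0.71). Lower too were Aen (-0.67), Ddit3 (-0.67) and Uqcrc2 (-0.30). Of these 30 calls 29, all but that of Aen, ended in at least 1 of the 12 fits without 1 library (adjusted p 0.0505 to 0.265). With the replicate number as a block 20 were kept, and those of Adam33, Ms4a7, Enpp2, Rgs5, Hist1h2ad, Serpinf2, Hormad2, Cdkn1a, Eda2r and Uqcrc2 ended (0.0509 to 0.105).

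A first pattern is the set of genes over 16-fold higher at 1 DPA, 328 of them with a position. The mean total count at 1 DPA, 0.829 of that of CTRL, argues against deeper sequencing. Read-through from an expressed gene within 10 kb upstream on the same strand may contribute to part of the set. Of it 35.4% (30.2 to 40.8) had such a neighbour against 9.83% of 1587 comparison genes (odds ratio 5.01, 3.75 to 6.70, Fisher's exact p = 1.06e-27). The share argues against such a source for most of the set. Farther ones were not tested. A downstream neighbour was less common in the set, at 17.1% (91 upstream only, 31 downstream only, exact binomial p = 4.99e-08), but its odds ratio was raised too (2.21, Fisher's exact p = 1.04e-05). Neighbours may themselves have risen, and comparison genes were matched only on an upper limit of CTRL expression, so a response to the ablation stays open, untested.

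A second pattern is the rise of mitosis genes at 5 DPA, 21 of 26 called with a median of 1.41 and a median standard error of 0.331. With the stromal score as a covariate the median was 1.08 with a standard error of 0.433, with the macrophage score 1.31 with 0.426, and edgeR called 0 with either, as the median fell and the standard error rose. With these scores camera still called the list (adjusted p = 4.67e-11 and 3.67e-14) but fry no longer did (0.213 and 0.168, against 0.0103 without), so whether more stromal cells or macrophages gave part or all of the rise cannot be told apart from a change in the islet cells. The count rests in part on 1 library, with 5 called without 5 DPA replicate 1 (median 1.01, standard error 0.308) and 7 and 8 without CTRL replicates 2 and 3. A proliferative response to the ablation may also contribute and was not separated from these by any test.

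The 6 libraries of a comparison split 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. The real count and the highest of the other splits were 8916 and 0 at 1 DPA, 2182 and 0 at 3 DPA, 1477 and 11 at 5 DPA. They were 7805 and 0 between 1 and 3 DPA and 547 and 0 between 3 and 5 DPA. Only the real split gave as many each time. Of 10 splits of the 3 and 5 DPA libraries 4, the real one included, part all 3 same-number pairs and 6 part 1 pair. All but the real one gave 0 genes with edgeR. Of 40 splits of the 12 libraries into 4 groups only the real one gave as many genes as the F-test's 9933. The highest other gave 0, so chance alone is unlikely there. Batch effects were not tested.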

How the results depend on the processing

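The macrophage and stromal covariates were chosen after the result was seen, and the other settings here were planned. The counts of changed genes at 1 DPA and over the 4 groups stayed within 1.5 times under every setting run, and those between 1 and 3 DPA under all but these 2 covariates. Of the 8916 genes called at 1 DPA and 7805 between 1 and 3 DPA, 6001 and 3672 were called with the macrophage covariate and 330 and 280 had the other direction. Of the values below that changed, the cause was not tested, except that fits with fewer libraries or only 2 groups have less information on the spread. Of 81 named calls at 1 DPA, 47 at 3 DPA and 55 at 5 DPA, DESeq2 kept all, limma-voom 67, 47 and 52, and fits of only the 2 groups 74 of 78, 37 of 47 and 27 of 54.

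With DESeq2, 942 genes were lower at 3 DPA and 2400 changed at 5 DPA (1545 higher, 855 lower). Between 3 and 5 DPA 1177 changed (416 and 761), and 513, 491 and 424 were lower in both of 1 and 3, 3 and 5, and 1 and 5 DPA. With limma-voom Ppy and Top2a at 3 DPA were at 0.0107 and 0.0103, on the other side of 0. Without the 50 most abundant genes Mafa at 1 DPA was -0.0556 and 289 genes were lower at 5 DPA. With no filter 307 were lower at 5 DPA and 266 between 3 and 5 DPA. With only the 2 groups compared, 222 were lower at 3 DPA, 622 changed at 5 DPA (418 and 204) and 899 between 3 and 5 DPA (278 higher). The shared calls were 963 and 142 for 1 and 3 DPA, 372 and 69 for 3 and 5 DPA and 312 and 102 for 1 and 5 DPA.

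Except perhaps between 3 and 5 DPA the replicate numbers did not pair the libraries: 4 of 18 same-number pairs had deviations correlated above 0.1, 3 of them between 3 and 5 DPA, and 4 of 12 libraries correlated best with their own number. With the replicate block Top2a at 3 DPA was 0.0200 and 340 genes changed between 3 and 5 DPA, 241 lower. Of named calls it ended 2 of 81, 6 of 47 and 7 of 55 at 1, 3 and 5 DPA and 3 of the 8 named for size between 3 and 5 DPA. In that order the acinar covariate ended 11, 18, 7 and 5, the macrophage one 28, 0, 42 and 5 and the stromal one 16, 6, 47 and 7. Between 3 and 5 DPA the block changed no camera call and, beyond the counts given beside the lists, moved no list's count of called members by over 1.5 times (G2/M 11 to 15, G1/S 8 to 10).

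With the acinar covariate 1372 genes changed at 3 DPA (172 lower), Ins2 and Top2a at 3 DPA were 0.0375 and 0.16, and Gcg at 5 DPA was -0.10. Then 204 genes changed between 3 and 5 DPA (29 and 175) and 93 and 126 were lower in both of 1 and 3 and of 3 and 5 DPA, and the acinar list between 3 and 5 DPA turned to the other direction (adjusted p = 0.997). With the macrophage covariate the 1 DPA values of Samsn1, Il33, Ltb, Plac8, Csf3r, Cd4 and Mafa were 0.19, 0.18, 0.10, 1.07, 0.26, 1.37 and -0.28. Ppy at 3 DPA was 0.12, and Ins1, Ins2 and Mafa at 5 DPA were 0.13, 0.0398 and 0.00494. Then 163 genes changed at 5 DPA (137 and 26), 4341 between 1 and 3 DPA (1701 and 2640) and 224 between 3 and 5 DPA (18 and 206). Higher and lower calls shared were 132 and 13 for 3 and 5 DPA and 110 and 5 for 1 and 5 DPA. Lists that turned to the other direction were the inflammatory list (camera adjusted p = 0.00894 at 1 DPA, 0.639 at 5 DPA, 0.643 between 1 and 3 DPA) and the interferon list (6.26e-06 at 5 DPA, 0.0593 between 1 and 3 DPA, 0.0014 between 3 and 5 DPA). So did macrophage genes at 5 DPA (0.917) and phagocyte and monocyte genes between 3 and 5 DPA (0.917 and 0.236). With it 5 lists were called at 1 DPA and 3 between 1 and 3 DPA. With the stromal covariate Mafa at 1 DPA was -0.0669, Ins2 and Ppy at 3 DPA were 0.0141 and 0.28, and Ins1, Ins2 and Gcg at 5 DPA were 0.15, 0.0559 and -0.0102. Then 72 genes changed at 5 DPA (68 and 4). Between 1 and 3 DPA 4691 changed (1812 higher) and between 3 and 5 DPA 104 (7 and 97), and the shared calls were 68 and 4 for 3 and 5 DPA and 63 and 2 for 1 and 5 DPA. The immature beta cell, phagocyte and interferon lists at 5 DPA turned to the other direction (0.912, 0.759 and 0.207), and 8, 7 and 8 lists were called at 5 DPA, between 1 and 3 DPA and between 3 and 5 DPA.

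With an estimated correlation camera called 0 lists in each of the 5 comparisons. At 1, 3 and 5 DPA, between 1 and 3 DPA and between 3 and 5 DPA the preset called 9, 6, 14, 14 and 14 and fry 11, 2, 14, 17 and 0. Leaving out 1 library at a time, the ranges were -0.0704 to 0.21 for Mafa at 1 DPA. At 3 DPA 1372 to 2801 genes changed, 1128 to 1806 higher and 180 to 995 lower, Ppy -0.36 to 0.38, Mafa -0.27 to 0.00127 and Top2a -0.18 to 0.22. At 5 DPA they were 462 to 2137 changed, 405 to 1330 higher and 57 to 807 lower, Gcg -0.17 to 0.23 and Ppy -0.0704 to 0.63. Between 3 and 5 DPA they were 31 to 1018 changed, 3 to 384 higher and 23 to 634 lower. Shared calls ranged from 987 to 1495 higher and 109 to 560 lower for 1 and 3 DPA, 362 to 714 and 48 to 472 for 3 and 5 DPA, and 323 to 613 and 38 to 390 for 1 and 5 DPA. Depth limits genes with few counts, and Hist1h2ad and Hormad2 had 0 CTRL counts and allow lower bounds only.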

Other observations

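The clock gene lists and their test were chosen after the result was seen, and these genes lie outside the rule for named genes.

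Genes of the circadian clock driven by E-box and D-box elements were higher at 1 DPA: Nr1d1 by 5.03 ± 0.50 (log2 fold change ± SE, n = 3, edgeR adjusted p = 2.86e-05), Per1 by 3.57 ± 0.39, Dbp by 3.28 ± 0.46 and Ciart by 7.23 ± 1.01. Of 10 such genes 10, 8 and 5 were called higher at 1, 3 and 5 DPA. Nr1d1 stood at 4.57 ± 0.49 at 3 DPA and 2.87 ± 0.46 at 5 DPA. Not called were Per2 (0.59 ± 0.19) and Per3 (-0.25 ± 0.23) at 3 DPA and, at 5 DPA, Dbp, Tef, Per2, Per3 and Bhlhe41 (1.52, 0.48, 0.29, -0.38 and 0.43). Harvest at another time of day may shift such genes, and would lower Arntl, Npas2, Clock and Nfil3 if exactly opposite in phase. At 1 DPA their median was 1.18, with Arntl (1.94 ± 0.11) and Nfil3 (3.37 ± 0.17) higher and Npas2 (0.42 ± 0.18) and Clock (-0.00 ± 0.09) not called. On that untested premise this argues against time of day as the whole cause. At 3 DPA the median was 0.149 over members going both ways. Arntl (0.43 ± 0.11, edgeR adjusted p = 0.0186) and Nfil3 (1.29 ± 0.16, 0.000338) were called higher, against such a shift, and Npas2 (-0.13 ± 0.18, 0.713) and Clock (-0.26 ± 0.09, 0.0714) were not called, so time of day cannot be told apart from a response to the ablation there. Harvest times are not in the sources used here.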
